A study of Mus musculus with 16 samples.

How the data were processed

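RNA was extracted from the ipsilesional and contralesional primary motor cortex of 8 mice after stroke with Trizol and an RNeasy kit, with RNA integrity numbers of 7 to 9, and poly(A) libraries were made with a stranded TruSeq kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, Trimmomatic 0.38, STAR 2.5.1b, edgeR and the mm10 build, without giving the role of each. The read counter, the annotation and the rule by which genes were selected are not given in the sources used here. Samples were grouped by their titles into recovered (n = 3) and non-recovered (n = 5) in each hemisphere; the labels name each as a separate animal.

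The authors deposited a table per hemisphere that holds log2 CPM values per library for selected genes, with no fold changes or p-values. The deposited log2 values are whole reads plus a prior count of 2, scaled by the library total, as counts per 1000000 reads. Solving for this, 100% of values came out as whole reads within 0.01 (largest departure 0.000124). This gave each gene's reads and the total by which each library was scaled. Whether that total is the plain read total or already includes a normalization factor cannot be told from the values. The listed genes held 2.55 ± 0.07% (SD, n = 8) of the ipsilesional and 1.53 ± 0.03% (SD, n = 8) of the contralesional totals. Genes in each table stand in the order of their fold change (Spearman rho = 0.999 in each, across genes). The tables were normalized separately, so no level was compared between hemispheres and the planned comparison of ipsilesional with contralesional cortex was not run. Because both tables are selections made on the same libraries, values of the other genes were not analysed here, no gene set test against all genes was possible, and p-values adjusted within a table can be smaller than they would be over all tested genes.

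Recovered and non-recovered libraries were compared within each table by limma 3.58.1 in R 4.3.3 on the deposited log2 CPM, with no filter and no pseudocount of its own beyond the prior count. Benjamini-Hochberg adjustment ran over the listed genes. The design fixed beforehand assumed counts or linear values, so this differs from it in scale; log2(CPM + 1) and log2(CPM + 0.1) were run as alternatives. Fold changes of genes with few reads are understated by the prior count. With 3 against 5 animals the exact permutation test has 56 splits and a smallest p of 0.0179. Data were simulated from the real means and totals, with 200 changed genes and the listed genes' median dispersion for every gene (0.0051 ipsilesional, 0.0039 contralesional). In them limma found 100% of 2-fold and 98% of 1.4-fold changes among 263 ipsilesional genes and called 5 of 63 unchanged ones. It found 100% and 90% among 417 contralesional genes, with 7 of 217 unchanged ones called. With no change simulated it called 0 in either, and 4.94% and 7.19% of genes had an unadjusted limma p under 0.05. Real genes differ in spread, and the listed ones were selected, so these rates do not give the power for genes of wider spread. The within-group length test was tested on simulated data too, with permutation p = 0.566 without a trend and 0.0001, the smallest that 10000 permutations can give, with one.

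Named genes were chosen by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls, the 5 smallest p in each direction, members of 23 fixed lists, genes past the threshold in both hemispheres, and Adora2a, Drd2 and Pde10a. The rule takes the authors' p, and as the tables give none, the unadjusted limma p of 0.05 took its place. Lists with 3 or more listed members were tested by Fisher's exact test on direction against the rest of the table, with Benjamini-Hochberg adjustment over lists. Further gene groups were picked after the values were seen and are named as such. Coordinates and exonic lengths came from GENCODE M21 on GRCm38, the assembly behind mm10. All 263 ipsilesional symbols and 414 of 417 contralesional ones were matched, 3 of them through a newer symbol. Coordinates are 1-based and cover the whole gene.

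Recovery differences were compared between hemispheres for the 19 genes in both tables, as the difference of the fold changes within each table. The design had set this aside for separately normalized tables; it was run because a scale shared by all libraries of a table cancels within its fold change. The animal number pairs the libraries, since they come from the same animals, except that titles and descriptions disagree on which contralesional library belongs to animal 6 and which to 23. Deviations from the group means correlated across the 19 genes by 0.41 on average for the same number and 0.41 for the same description code, against -0.07 for other pairs. For animals 6 and 23 the correlations were -0.06 and 0.33 by number, and for the ipsilesional libraries of 6 and 23 they were 0.11 and 0.21 by code, which does not settle the conflict. Both animals are recovered, so comparisons within a hemisphere are not affected. None of the 26 pairs of libraries within a group agreed within counting noise (chi-square per gene at least 2.73), so no library was counted as a duplicate. Columns left unused because they belong to other samples numbered 0.

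Alternatives covered quantile normalization, both pseudocounts, genes with mean log2 CPM above 1, other thresholds and adjustments, each library left out in turn, the animal block, and, added after seeing the data, voom on recovered reads, adjustment over 22028 annotated protein-coding genes, removal of a trend on exonic length and pairing by description code. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps. Depth limits the low genes: Drd2 had 9 to 60 reads per library. Values of some single genes are not reported here, and 1 of them was left out of the plot of striatal genes, though counts and list statistics include them.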

Results

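Messenger RNA was sequenced from the primary motor cortex of 8 C57Bl6 mice after stroke. Recovery of movement had been judged on a horizontal rotating beam, on which a mouse has to keep its balance while walking. The labels place 3 animals in a spontaneously recovered group (animals 6, 23 and 28) and 5 in a non-recovered group (animals 17, 19, 20, 21 and 29). The cortex was taken from both hemispheres of each animal, on the side of the lesion (ipsilesional) and on the opposite side (contralesional), which gave 16 libraries. The deposited tables hold log2 CPM (counts per 1000000 reads) of selected genes only, 263 in ipsilesional and 417 in contralesional cortex. The totals by which libraries were scaled, recovered from the values, ranged from 19116419 to 26310885 in ipsilesional and from 17972791 to 27895465 in contralesional cortex. They may include a normalization factor and so need not be plain read totals. In contralesional cortex they were 21.9 ± 3.81 M in recovered (SD, n = 3) and 25.5 ± 2.98 M in non-recovered libraries (SD, n = 5, exact permutation p = 0.214, 2-sided). Throughout, a log2 fold change is the mean log2 CPM of recovered minus that of non-recovered animals, given with its standard error (SE) from limma.

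The first comparison asked which genes distinguished recovered from non-recovered mice in the cortex next to the lesion. Of the 263 genes listed there, 131 were higher and 132 lower in recovered mice, with a median absolute log2 fold change of 0.26. The 3 genes with a limma adjusted p under 0.05 all fell. Jsrp1, a protein of the sarcoplasmic reticulum junction in muscle (mm10 chromosome 10, 80808496 to 80813498, minus strand), fell from 2.26 ± 0.07 log2 CPM (SD, n = 5) to 1.82 ± 0.07 (SD, n = 3; log2 fold change -0.44 ± 0.06, adjusted p = 0.0224). Cpxm2, a member of the carboxypeptidase family (chromosome 7, 132032687 to 132154739, minus strand), fell from 1.30 ± 0.10 to 0.78 ± 0.15 (-0.52 ± 0.09, adjusted p = 0.0416). Ankrd6, an ankyrin repeat protein of the Wnt pathway (chromosome 4, 32804035 to 32950841, minus strand), fell from 5.10 ± 0.07 to 4.72 ± 0.10 (-0.38 ± 0.07, adjusted p = 0.0416). Jsrp1 had 77 to 129 reads per library and Cpxm2 34 to 65. At such counts the SDs of few libraries, in genes selected on them, can understate the spread, and this fit gave no weight to read number. With voom, which does, no gene passed (smallest adjusted p = 0.0506).

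Further ipsilesional genes were ranked by fold change among those with an unadjusted, but no adjusted, limma p under 0.05. Of these, lower in recovered mice by the largest amounts were Aox3, an aldehyde oxidase (-1.06 ± 0.28), Lyve1, a hyaluronan receptor of lymphatic vessels and border macrophages (-0.95 ± 0.22), Krt73 (-0.69 ± 0.18) and Lmntd1 (-0.68 ± 0.20). Next came Bub1b, a kinase of the mitotic checkpoint (-0.67 ± 0.13), the retinol transporter gene Stra6 (-0.65 ± 0.27), Tbx18, a transcription factor of meningeal and mural cells (-0.62 ± 0.23), and Pcsk4 (-0.61 ± 0.26), beside Lrrc10b and Hif3a, which are given with their lists. Lonrf3 (-0.32 ± 0.06) was among the 5 lower genes with the smallest p. The largest positive differences among genes past that p belonged to Hpse, which encodes heparanase (0.86 ± 0.35), Pidd1 (0.74 ± 0.17), Zpbp (0.63 ± 0.14) and Ncaph, a condensin subunit (0.57 ± 0.21). Smaller ones were those of Bbs12 (0.47 ± 0.16), Xrra1 (0.46 ± 0.15) and Pcdha3, a clustered protocadherin whose exons overlap those of its neighbours (0.45 ± 0.17). Casp1, the inflammatory caspase (0.45 ± 0.15), Ide, the insulin-degrading enzyme (0.42 ± 0.13), and Mybpc1 (0.42 ± 0.12) followed. Cyp2s1 (0.35 ± 0.08), Nefh, the heavy neurofilament chain (0.31 ± 0.08), and Plxdc1 (0.23 ± 0.06) had some of the smallest p among higher genes.

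Of the 23 gene lists fixed before the data were examined, 14 had a member in the ipsilesional table, and 4 had the 3 members needed for a test of direction. None of the 4 passed (Fisher's exact test, 2-sided, of higher against lower for members against the other listed genes). Meningeal fibroblast genes numbered 3, all lower: the prostaglandin D synthase gene Ptgds (-0.58 ± 0.29) and the transporters Slc22a6 (-0.57 ± 0.34) and Slc6a20a (-0.53 ± 0.26). Their adjusted Fisher p was 0.494, with no member at an unadjusted limma p under 0.05. Glucocorticoid-responsive genes also numbered 3, all lower, with Hif3a (-0.59 ± 0.18) and Sult1a1 (-0.34 ± 0.12) past the unadjusted p and Plin4 (-0.72 ± 0.36) not (adjusted Fisher p = 0.494). Of 4 channel and synapse genes, the potassium channel gene Kcna1 (0.22 ± 0.09), the sodium channel gene Scn1a (0.27 ± 0.10) and the muscarinic receptor gene Chrm4 (0.27 ± 0.14) were higher and the postsynaptic scaffold gene Dlg4 (-0.18 ± 0.08) was lower (adjusted Fisher p = 0.494). Striatal projection neuron genes split, with Lrrc10b (-0.60 ± 0.23) and Pde10a, a cyclic nucleotide phosphodiesterase (-0.32 ± 0.13), lower and the sodium channel subunit gene Scn4b (0.27 ± 0.12) higher (Fisher p = 1). Both listed genes of inhibitory interneurons were higher, the GABA-synthesising enzyme gene Gad1 (0.22 ± 0.08) and the vesicular transporter gene Slc32a1 (0.15 ± 0.06). Single members of other lists were the heat shock gene Hspb1 (-0.58 ± 0.22; also on the reactive astrocyte list), Bmp4 of the oligodendrocyte lineage (-0.47 ± 0.16) and Calb1 of excitatory neurons (-0.23 ± 0.10). So were the guidance gene Sema3e of the axon growth list (0.27 ± 0.12), Zic1 of thalamic neurons (-0.51 ± 0.26) and the activity-dependent transcription factor gene Npas4 (-0.97 ± 0.44). Pde10a was the only listed member of the cAMP and dopamine list. Adjusted over the list alone, members past 0.05 numbered 3 for striatal, 2 for glucocorticoid and 2 for interneuron genes, and 0 for meningeal and channel genes. These counts are not independent evidence, because the authors' table already holds genes selected on these samples. Several fold changes shrank when 1 recovered library was left out. Without animal 23 they were -0.34 for Ptgds, -0.35 for Slc22a6, -0.32 for Slc6a20a, -0.25 for Zic1 and -0.35 for Tbx18, and without animal 28 they were 0.11 for Chrm4 and 0.17 for Scn1a.

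Markers of microglia and complement were high in 1 ipsilesional library. In animal 6 of the recovered group, Gpnmb reached 6.50 log2 CPM, against at most 3.19 in the 7 others, C3 reached 5.12 against at most 1.91, and Itgam 4.47 against at most 2.98. The group difference was 1.32 ± 1.16 for Gpnmb, 0.34 ± 1.57 for C3 and 0.59 ± 0.41 for Itgam (limma adjusted p = 0.291, 0.835 and 0.191), and without that library it was -0.39, -1.86 and -0.0067. Other differences also shrank without it, from 0.86 to 0.51 for Hpse, 0.57 to 0.37 for Ncaph, -0.18 to -0.085 for Dlg4 and -0.23 to -0.13 for Calb1. Animal 6 carries the only ipsilesional description code with a different prefix.

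**Figure D1:**
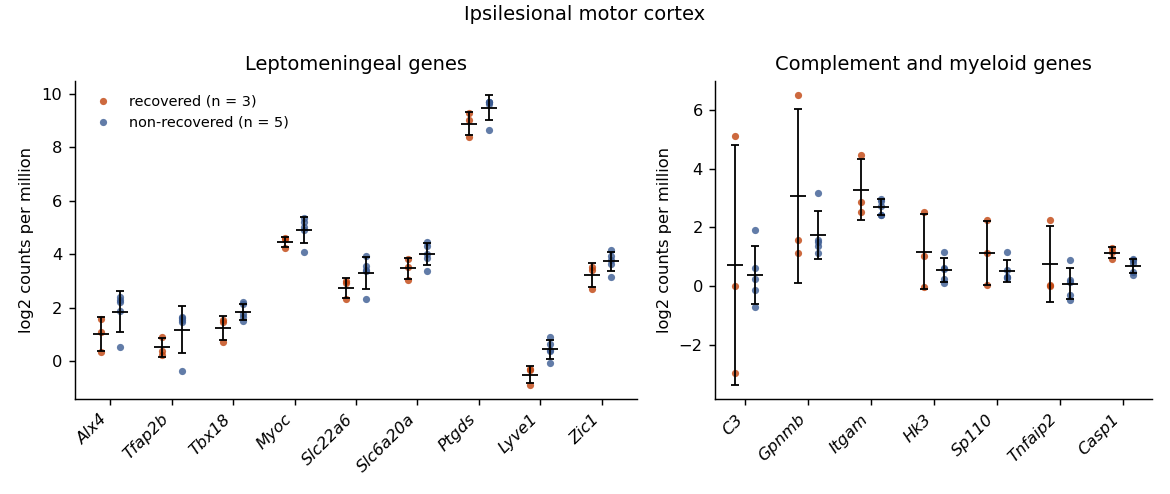
Log2 CPM in ipsilesional motor cortex of 9 leptomeningeal genes (left) and 7 complement and myeloid genes (right), chosen after the values were seen. Points are libraries of recovered (n = 3) and non-recovered (n = 5) mice, bars are the mean and SD. On the right, 1 recovered library (animal 6) lies far above the others, with Gpnmb at 6.50, except for Casp1. There animal 6 is at 1.31 and recovered animal 28 at 1.16.

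The ipsilesional count of 3 genes was adjusted over the 263 listed genes alone, which were already selected on these libraries. At an unadjusted p under 0.05 limma called 196 genes, 98 in each direction; the adjusted count was 0 when it was taken over all annotated protein-coding genes, 0 with voom on the recovered reads (222 unadjusted), and 39 after quantile normalization (15 higher, 24 lower). It was 0 without animal 17, 21 or 23, 1 without 20, 6 without 6, 7 without 29, 13 without 19 and 18 without 28.

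In contralesional motor cortex, the question was whether the hemisphere opposite the lesion also differed with recovery. There 147 listed genes were higher and 270 lower in recovered mice, with a median absolute log2 fold change of 0.26. By limma, 33 passed an adjusted p of 0.05, 25 of which fell and 8 of which rose. Naaladl2, a peptidase-like gene (chromosome 3, 23798102 to 25144261, minus strand), fell from 2.29 ± 0.11 log2 CPM (SD, n = 5) to 1.78 ± 0.05 (SD, n = 3; -0.51 ± 0.08, adjusted p = 0.0281). Gk5, of the glycerol kinase family (chromosome 9, 96119362 to 96184608, plus strand), fell by 0.59 ± 0.09 on the log2 scale, and Cox16, a cytochrome c oxidase assembly factor (chromosome 12, 81359026 to 81485127, minus strand), fell by 0.52 ± 0.09 (adjusted p = 0.0281 and 0.0330). At adjusted p = 0.0469, Gpr6, an orphan receptor of striatal neurons (chromosome 10, 41069977 to 41072285, minus strand), fell by 0.71 ± 0.18, the prostaglandin E2 receptor gene Ptger4 by 0.63 ± 0.16, Crispld1 by 0.61 ± 0.15. The centromere gene Cenpl fell by 0.53 ± 0.11, and Mgp, matrix Gla protein, by 0.40 ± 0.09. Sema5b, a semaphorin (chromosome 16, 35541145 to 35664732, plus strand), rose by 0.44 ± 0.08 and Micall2 by 0.42 ± 0.09. The phosphatidylcholine transfer protein gene Pctp rose by 0.49 ± 0.12, the cilia gene Cfap65 by 0.49 ± 0.11 and the zinc finger gene Zfp580 by 0.34 ± 0.08 (adjusted p = 0.0469 for each).

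Further contralesional genes were ranked among those past the unadjusted p alone. Lower in recovered mice were Drd2, the dopamine D2 receptor gene (chromosome 9, 49340627 to 49408177, plus strand; -1.31 ± 0.43, adjusted p = 0.0564), and Npas4 (-1.06 ± 0.44). The cell division genes Cdca7 (-0.80 ± 0.23) and Bub1b (-0.73 ± 0.30) followed, with Adora2a, the gene of a striatal adenosine receptor (chromosome 10, 75316877 to 75334784, plus strand; -0.73 ± 0.32, adjusted p = 0.0678), the potassium channel subunit gene Kcne4 (-0.61 ± 0.17), and Rxrg (-0.59 ± 0.25). Higher were the beta-globin genes listed as Hbb.bt (1.02 ± 0.40) and Hbb.bs (0.79 ± 0.26), whose near-identical sequences leave the share of each uncertain. Also higher were the thyrotropin-releasing hormone receptor gene Trhr (0.85 ± 0.25), Dcaf12l2 (0.57 ± 0.22), Skap1 (0.54 ± 0.21), Foxo6 (0.50 ± 0.14), Prss22 (0.48 ± 0.14) and Psmg4 (0.45 ± 0.15).

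Striatal projection neuron genes formed the fullest contralesional list, with 10 listed members, all lower in recovered mice. Their median log2 fold change was -0.60. Besides Gpr6, Drd2, Adora2a and Rxrg, Pde10a (chromosome 17, 8525372 to 8986648, plus strand; -0.50 ± 0.16, adjusted p = 0.0520) passed the unadjusted p, and Lrrc10b (-0.74 ± 0.35), Syndig1l (-0.61 ± 0.40), the enkephalin gene Penk (-0.25 ± 0.13) and Rasd2 (-0.18 ± 0.08) did not. Drd2 had 9 to 60 reads per library, Adora2a 35 to 128 and Pde10a 1064 to 2004. Against the rest of the table, where 147 genes were higher and 260 lower, the excess of lower members gave Fisher p = 0.0168 and adjusted p = 0.0841 over the 5 lists tested. The test treats genes as independent, but the members varied together within groups (median pairwise r = 0.58), so these p-values can be too small. Only Gpr6 passed an adjusted p over all listed genes, and 3 members passed when adjusted over the list alone, which is not independent evidence for a table selected on these samples. Averaged over the 10 genes as deviations from each gene's mean, the recovered libraries lay at -0.38 ± 0.05 (SD, n = 3) and the non-recovered ones at 0.23 ± 0.40 (SD, n = 5; exact permutation p = 0.0714, 2-sided). The non-recovered animal 29 lay at -0.37, among the recovered animals.

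**Figure D2:**
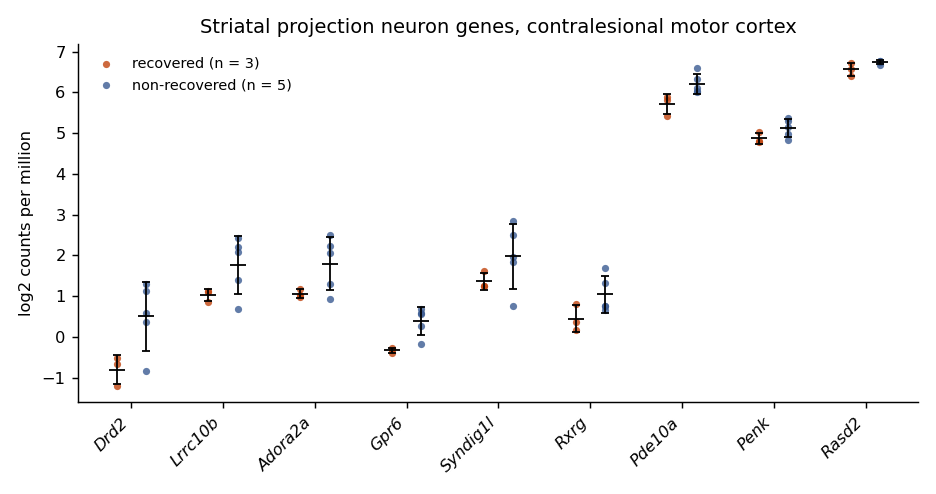
Log2 CPM of 9 of the 10 listed striatal projection neuron genes in contralesional motor cortex. Points are libraries of recovered (n = 3) and non-recovered (n = 5) mice, bars are the mean and SD; all 9 means are lower in recovered mice, from -1.31 for Drd2 to -0.18 for Rasd2.

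Of the other contralesional lists, none passed. The cAMP and dopamine list had 5 members past the unadjusted p, of which Drd2, Adora2a, Pde10a and the phosphodiesterase gene Pde7b (-0.35 ± 0.14) were lower and the dopamine D5 receptor gene Drd5 (0.41 ± 0.17) higher (adjusted Fisher p = 0.826). Glucocorticoid-responsive genes were lower in 3 of 3 cases, with the kinase gene Sgk1 (-0.25 ± 0.08) and Tsc22d3 (-0.17 ± 0.07) past the unadjusted p and Hif3a (-0.47 ± 0.22) not (adjusted Fisher p = 0.826). Meningeal fibroblast genes were also lower in 3 of 3, where Mgp passed and Islr (-0.33 ± 0.16) and fibronectin, Fn1 (-0.22 ± 0.11), did not (adjusted Fisher p = 0.826). In the axon growth list the transcription factor gene Sox11 (-0.33 ± 0.11) and the growth factor gene Igf1 (-0.24 ± 0.10) were lower and Sema3e (0.25 ± 0.12) higher (Fisher p = 1). Immediate early genes were represented by Npas4 and Btg2 (-0.53 ± 0.27), both lower, and interneurons by the somatostatin gene Sst (0.14 ± 0.07), which turned to -0.12 with the trend on exonic length removed. Single members of other lists included H2.T23 of the reactive astrocyte list (0.43 ± 0.12), the heat shock list's Creld2 (-0.24 ± 0.10), and Cfap65 of the ependymal list. Adjusted over the list alone, members past 0.05 numbered 5 for cAMP and dopamine, 2 for glucocorticoid, 2 for haemoglobin and 1 each for meningeal and axon growth genes. Here too, fold changes shrank when 1 library was left out. Without animal 28 they were -0.10 for Fn1, -0.13 for Islr, -0.14 for Igf1, 0.27 for H2.T23 and 0.52 for Hbb.bs. They were -0.28 for Hif3a and -0.64 for Npas4 without animal 6, -0.09 for Rasd2 without animal 23, and -0.40 for Syndig1l without animal 21. No member of the peripheral leukocyte, endothelial, choroid plexus, hypothalamic, sex-linked or ribosomal and mitochondrial lists was listed in either table.

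Exonic length moved with the contralesional difference. It counts the bases covered by any annotated exon of a gene, so it is not the length of a single transcript. The lower genes had a median exonic length of 6669.5 nt and the higher ones 3073.5 nt, a ratio of 2.17 (95% bootstrap interval 1.83 to 2.44; permutation p = 1e-05, the smallest that 100000 permutations can give; 414 genes, which are not independent replicates). In ipsilesional cortex the medians were 5125.5 and 5343 nt, a ratio of 0.96 (0.76 to 1.06; permutation p = 0.517). For each contralesional library, log2 CPM was taken as the deviation from each gene's mean over all libraries of the hemisphere. Per doubling of length this deviation changed by -0.02, -0.04 and -0.11 in recovered animals 6, 28 and 23, and by 0.02 to 0.04 in the non-recovered ones. Slopes of deviations balance across the libraries, so their opposite signs in the groups restate the length difference and add no separate evidence. The library of animal 23 carries the only contralesional description code with a different prefix, the same code as the ipsilesional library of animal 6.

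**Figure D3:**
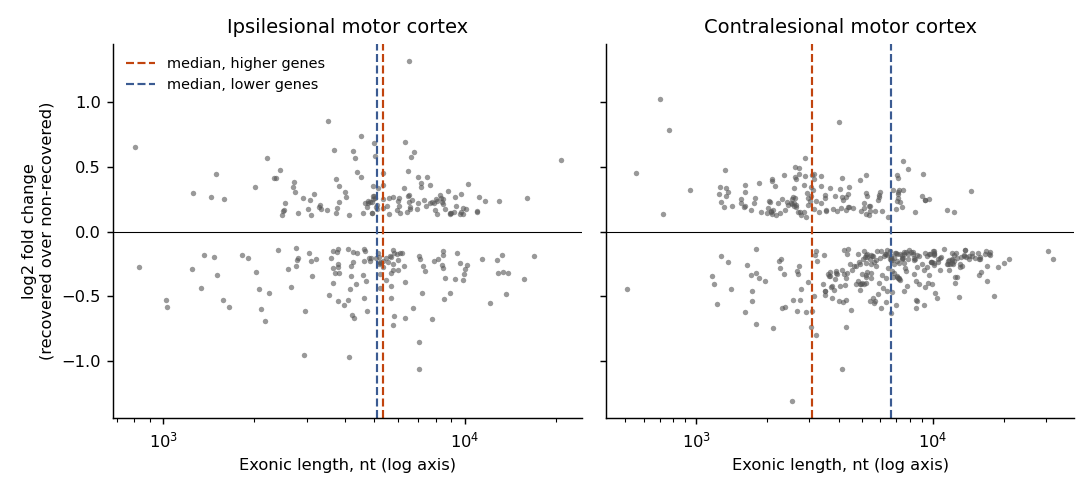
Log2 fold change (recovered over non-recovered) of each listed gene against its exonic length in nt on a log axis, in ipsilesional (263 genes) and contralesional (414 genes) motor cortex. Dashed lines mark the median length of higher and lower genes, 3073.5 and 6669.5 nt in contralesional cortex and 5343 and 5125.5 nt in ipsilesional cortex.

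The contralesional count of 33 was likewise adjusted over selected genes. Unadjusted, limma called 306 genes, 107 higher and 199 lower. The adjusted count was 0 over all annotated protein-coding genes, 0 with voom (356 unadjusted) and 3 on log2(CPM + 1). After quantile normalization it was 77, with 70 higher and 7 lower. That step forced equal distributions on a table with more lower than higher genes, which can turn the balance by itself. Leaving out 1 library gave 0 genes without animal 17, 1 without 20, 3 without 19, 6 without 28, 10 without 21, 16 without 23, 58 without 6 and 74 without 29.

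The hemispheres were then compared through the genes that both tables list. There were 19 such genes, and 18 had the same direction on both sides, 6 higher and 12 lower in recovered mice (94.7%). Npas4 was lower by similar amounts (-0.97 ± 0.44 and -1.06 ± 0.44), as were Bub1b (-0.67 ± 0.13 and -0.73 ± 0.30), Lrrc10b (-0.60 ± 0.23 and -0.74 ± 0.35), Pde10a (-0.32 ± 0.13 and -0.50 ± 0.16) and the signalling gene Smad3 (-0.24 ± 0.09 and -0.19 ± 0.08). Higher on both sides were, among others, Ide (0.42 ± 0.13 and 0.32 ± 0.11), N4bp3 (0.31 ± 0.11 and 0.44 ± 0.13), the secretogranin gene Scg2 (0.17 ± 0.07 and 0.22 ± 0.08) and Ahdc1 (0.21 ± 0.09 and 0.16 ± 0.06). Of the 19, 8 passed an unadjusted limma p of 0.05 on both sides and 0 passed an adjusted one. Both tables were selected on the same animals and the same split, which favours equal directions. A binomial test of the agreement against 0.5 (p = 7.63e-05, 2-sided) therefore cannot weigh it against chance, and no conclusion is drawn from it. The background of tested genes was not given in the sources used here, so no enrichment of the overlap was tested.

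**Figure D4:**
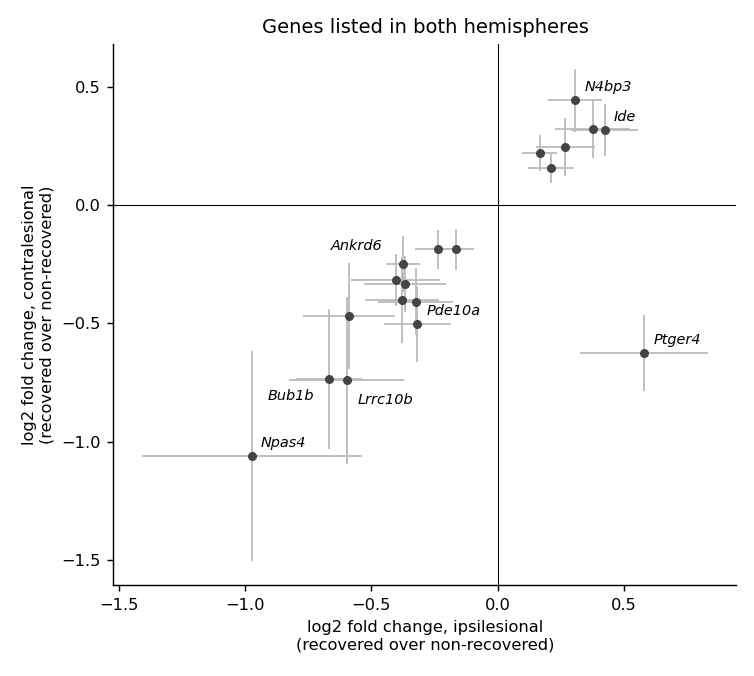
Log2 fold change (recovered over non-recovered) in contralesional against ipsilesional motor cortex for the 19 genes listed in both, with SE from limma as bars. Of these, 18 lie in the quadrants of equal direction; Ptger4 lies at 0.58 and -0.63.

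Ptger4 was the gene with opposite directions. It was higher in recovered mice next to the lesion (0.58 ± 0.25, adjusted p = 0.0668) and lower on the other side (-0.63 ± 0.16, adjusted p = 0.0469), with 13 to 65 reads per library. Its ipsilesional level was highest in animal 6, and without that library the rise fell to 0.34. The difference between these fold changes was 1.21 ± 0.32 (limma adjusted p = 0.0368 over the 19 genes, and 0.0039 with the animal as a block by title number). None of the other 18 genes passed (smallest adjusted p = 0.931). All 19 genes had already been selected on these same libraries. Such selection favours a large hemisphere difference for a gene with opposite signs and a small one for the rest. These p-values are therefore not independent evidence. With the animals paired by description code, 0 genes passed, and Ptger4 remained past 0.05 in 7 of 16 fits that left out 1 library.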

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

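All tests weighing explanations here were chosen after the results were seen. A non-recovered library lay apart from the 4 others of its group in 14 of 188 sets of values looked at, where chance gives about 9.4. The gap to the nearest library, as a share of the group's range, exceeded 0.71 in each. The sets share the same libraries, so the count can stray further from 9.4 than with independent sets. That cutoff is for 5 samples and no recovered library was flagged, so recovered animal 6 (Gpnmb at 6.50) is not among them. Next to the lesion, animal 19 was lowest for Ptgds (share 0.916; 8.65 log2 CPM against 9.62 to 9.71), Tfap2b (0.899), Alx4 (0.717) and Aox3 (0.715). Animal 21 was highest for Gpnmb (0.776; 3.19 against 1.12 to 1.59) and Plxdc1 (0.715) and lowest for Kcns3 (0.723). Animal 20 was highest for Scn1a (0.776), and animal 17 lowest for Cnih2 (0.721). In contralesional cortex, animal 29 was highest for Ide (0.735) and lowest for Epha8 (0.730) and Islr (0.729), and animal 21 was lowest for Rasd2 (0.747) and Pcdhb6 (0.721). Ptger4 stood out because its recovery difference was of opposite sign in the hemispheres, by 1.21 ± 0.32 on the log2 scale (limma adjusted p = 0.0368), a call lost with the animals paired by description code (adjusted p = 0.118) and kept in 7 of 16 fits that left out 1 library. The shared genes had been selected on these libraries, so the Ptger4 p-values are not independent evidence.

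The first pattern is the size of the gene lists. If p-values were spread evenly, 10% of those under 0.05 would lie under 0.005. The share was 11.2% (exact 95% interval 7.17 to 16.5%) in ipsilesional and 11.8% (8.38 to 15.9%) in contralesional cortex, both of which chance across all tested genes may give. The share cannot decide this, because genes under 0.05 by limma that the authors did not list may be missing. The interval also treats genes as independent. A cutoff of 0.05 would list 263 genes by chance from 5260 tested and 417 from 8340, fewer than the 22028 annotated protein-coding genes, and the number tested is not known. Of the 56 splits of the libraries, 2 gave as many genes as the real ipsilesional split (3, highest other 5) and 1 as many as the contralesional one (33, highest other 6). These counts cannot exclude chance, because the genes were selected on the real split. The recovery of the animals stays open as the biological explanation of single genes.

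The second pattern is genes of adjoining tissue. Within groups, the 10 striatal genes in contralesional cortex varied together (median pairwise r across 8 libraries 0.58). The upper end of the central 95% of random lists of equal size and expression was 0.21. The 9 leptomeningeal genes in ipsilesional cortex did so more closely (0.83, against 0.23). Those 9 were picked from the lower genes after the values were seen, so their comparison with random lists decides nothing. Averaged as deviations from each gene's mean, non-recovered animal 19 lay at -0.56, against 0.33 to 0.54 in the others of its group. A varying share of striatal or meningeal tissue in the dissected pieces is a candidate source, and so is regulation of these genes together, including with recovery; the level of Rasd2 did not follow the mean of the other 9 striatal genes (r = -0.09). A single deciding library is argued against, since the median striatal fold change stayed between -0.76 and -0.47 with any library left out. Drd1, Ppp1r1b and Tac1, abundant in striatum, are not among the listed genes, which decides nothing.

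The third pattern is the greater exonic length of the genes lower in contralesional cortex. The libraries' slopes on length also differed within groups (permutation p = 0.0001, the smallest that 10000 permutations can give), most in recovered animal 23. A length bias of single libraries, such as RNA quality leaves, is a candidate source. The test cannot decide this, because length goes with direction among these selected genes. A library with a stronger group difference then has a steeper slope even without such a bias. Shuffling lengths also treats the genes as independent. A trend of the animals in both hemispheres is argued against by the ipsilesional ratio of median lengths, 0.96 (0.76 to 1.06). Removing the trend left 30 of 32 called genes past the adjusted p. Their median absolute log2 fold change was 0.44 before and 0.47 after, with a median SE of 0.09 and 0.10. A trend of this form thus did not account for the size of those differences. It was fitted on genes selected on this split, so the calls that remain do not exclude a length effect of another form. Recovery and length bias stay confounded in the group means, with 1 recovered library (animal 23) carrying the steepest slope. That library has the only contralesional description code with a different prefix, shared with the ipsilesional library of animal 6; whether the prefix marks a batch is not given in the sources used here, so a batch difference of these libraries stays open too.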

How the results depend on the processing

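Counts of genes past an adjusted p rest on the processing. The balance of higher and lower among the contralesional ones was 8 to 25, but 70 to 7 after quantile normalization. That step ran on the listed genes alone, of which 147 were higher and 270 lower. Forcing equal distributions on such a table raises the recovered libraries, so this turn can follow from the method and is no evidence on direction. The sign of single named genes rarely changed, which is favoured by choosing them for differences on these libraries. Alternatives added after seeing the data were the adjustment over all protein-coding genes, voom, the removed length trend, the pairing by description code, genes limited to an unadjusted p for shared genes and lists, and leaving out libraries for shared genes, lists and the hemisphere difference. Of the 1629 named-gene results under alternatives that kept all libraries, 1 reversed: Sst in contralesional cortex, at -0.12 with the length trend removed, by construction of that correction. Bonferroni adjustment, unadjusted p and adjustment over all protein-coding genes keep the main fold changes, so their part of these results could not reverse. Of 1488 with 1 library left out, 5 reversed, all ipsilesional without recovered replicate 6, where that library is the highest of 8; for C3, recovered animal 28 also had 1 read. Their ranges with 1 library left out were -1.86 to 2.17 for C3, -0.39 to 2.29 for Gpnmb, -0.0067 to 0.97 for Itgam, -0.044 to 1.23 for Hk3 and -0.065 to 1.07 for Tnfaip2. Few reads are a further limit for the low genes.

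Against 3 ipsilesional and 33 contralesional genes, quantile normalization gave 39 and 77, log2(CPM + 1) 1 and 3, Bonferroni adjustment 1 and 1, and removal of the length trend 31 and 71; the cause was not tested. Genes with mean log2 CPM above 1 gave 4 and 3. Unadjusted p gave 196 and 306, adjusted p under 0.1 gave 248 and 409, under 0.01 0 and 0, with an absolute log2 fold change of at least 1 0 and 0, and adjustment over all protein-coding genes 0 and 0, as other thresholds do by construction. Voom gave 0 and 0; the smallest adjusted p was 0.0506 and 0.0520. With 1 library left out the counts ranged from 0 to 18 and from 0 to 74, with fewer samples. log2(CPM + 0.1) gave 3 and 32.

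Of 18 shared genes with equal direction, 0 passed an adjusted p of 0.05 on both sides, 18 one of 0.1, 0 one of 0.01, 0 an absolute log2 fold change of 1, and 8 an unadjusted p of 0.05. Matching without regard to case gave 18, as did each left-out library. No gene list passed an adjusted Fisher p in any alternative that left lists to test; unadjusted, the contralesional striatal list alone passed with all listed genes (p = 0.0168). Restricting lists to large fold changes or to adjusted p under 0.01 left none to test, an estimated correlation needs all genes, and the main fit had no filter on low values to remove, so these were not run.

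With the animal as a replicate block, the recovery difference differed between hemispheres for 1 gene by title number and 1 without animals 6 and 23, as without the block, and for 0 with the pairing by description code. Leaving out 1 library gave 0 to 1: 0 without ipsilesional animal 6, 20 or 28 or contralesional animal 17, 19, 20, 21, 23 or 28. As the shared genes had been selected on these libraries, these counts are not independent evidence. The comparison of hemisphere levels was not run.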

Other observations

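Groups in this part were picked after the values were seen, from genes on 1 side of a table, so their shared direction carries no weight of its own. Next to the lesion, 12 of the genes with a higher mean in recovered mice are known from fast-spiking interneurons or large axons, without a test that such genes were overrepresented. Of them, 11 had an unadjusted limma p under 0.05 and 0 an adjusted one, and they included the synaptotagmin gene Syt2 (0.36 ± 0.14), the potassium channel subunit gene Kcns3 (0.29 ± 0.09), Lgi2 (0.23 ± 0.07) and the coactivator gene Ppargc1a (0.19 ± 0.08); without recovered animal 28, Syt2 fell to 0.23. The genes with a lower mean included 10 postsynaptic ones, 6 of them at an unadjusted p under 0.05 and 0 at an adjusted one, such as the dendrite gene Ddn (-0.27 ± 0.08), Shisa9 (-0.24 ± 0.07), the gene Cacng3 of an auxiliary protein of AMPA receptors (-0.22 ± 0.09) and Camkv (-0.15 ± 0.06). Without recovered animal 6, the fold changes of Ddn and Cacng3 shrank to -0.18 and -0.11.

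In contralesional cortex, the lower genes included 7 of cell division, of which Hmmr, the hyaluronan-mediated motility receptor (-0.54 ± 0.12), and Cenpl passed the adjusted p, while the repair gene Brca1 (-0.54 ± 0.20) and the centriole kinase gene Plk4 (-0.32 ± 0.12) did not; without recovered animal 23, Brca1 was at -0.33. All 3 listed contralesional genes annotated as long intergenic non-coding RNAs were lower, Miat (-0.42 ± 0.18), Meg3 (-0.50 ± 0.25) and Ftx (-0.47 ± 0.20). Without recovered animal 23, the library with the steepest slope on length, they shrank to -0.18, -0.18 and -0.26. Zinc finger genes, taken by symbol rather than by value, numbered 18, of which 14 were lower and 4 higher, a balance that did not differ from the rest of the table (Fisher p = 0.316).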
